A study of Homo sapiens with 6 samples.

How the data were processed

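The series holds 6 libraries of HEK293T cells, 3 treated with an siRNA against PRP5 and 3 with a negative control siRNA (30 nM, 48 h). Total RNA was extracted with TRIzol, made into libraries with a VAHTS Universal V6 kit and sequenced on an Illumina NovaSeq instrument as paired-end reads of 150 bp, per the labels. The authors deposited 1 table per library with the count of reads that cross each splice junction, uniquely mapped and multi-mapped reads apart, together with strand, motif, an annotation mark and the largest overhang. STAR 2.7.7a, SAMtools 1.3.1 and the build hg19 are named in the submitters' processing notes, and the settings and the annotation are not given in the sources used here. The tables hold raw counts with no normalization and no reads inside exons or introns, so unspliced RNA and genes without introns are not measured. The largest junction end on chromosome 1, at 249232794, fits hg19, and all coordinates are in that build, counted from 1.

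The tables listed 544671 junctions in all, of which 167748 were in every library. The annotation mark was set for 99.6% of junctions, and 57.0% of the marked junctions had fewer than 6 reads over the 6 libraries, so it was not used to tell known from unknown introns. The tables give no gene names, and the gene annotation used here, GENCODE 29, is in another build. Genes were therefore named by structure, a choice made after the tables were seen: an annotated gene was placed where at least 2 pairs of its neighbouring introns, with the exon between them, had the same lengths as junctions on the same chromosome and strand, with no conversion of coordinates. This placed 14103 of 22413 genes, 13125 of them protein-coding, and 0 when the search was made on another chromosome. Of unique reads, 95.0% were given to 1 gene, 0.533% lay on introns of more than 1 gene and were left out of gene sums, and 3.41% had no gene. In all, 216821 junctions with 95.5% of the unique reads matched an annotated intron. The start and end of a gene are those of its matched introns.

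Unique junction reads were summed per cluster of introns that share splice sites, the unit fixed before the data were examined for the case that no annotation of the build was given, and, as an added result, per matched gene. Counts were filtered with filterByExpr, normalized by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, limma 3.58.1, R 4.3.3) at a Benjamini-Hochberg adjusted p under 0.05. TMM factors for genes were 1.07, 1.07 and 1.08 in the controls and 0.927, 0.931 and 0.938 in the knockdown. Values are CPM, which is counts scaled by library total and TMM factor. The 23 gene lists were fixed before the data were examined and tested with camera (correlation preset at 0.01, and again estimated) and fry.

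A skipped exon is a set of 3 junctions, both inclusion junctions and the skipping junction, around an exon of 10 to 500 nt. Inclusion (PSI) is the mean of the inclusion junctions divided by that mean plus the skipping reads. Events needed a mean of at least 10 informative reads per library and 12 reads of the rarer form over the 6 libraries. The reads of both forms were tested with edgeR in a model with a term per library, a term for form and the interaction of form and knockdown, and an event was called at an adjusted p under 0.05 and a change of at least 0.1 in PSI or share. Alternative 3' and 5' sites, 3 to 200 nt from the most used site, were tested in the same way. The most used site is the one with the most reads over the 6 libraries together, so an alternative site can be the more used one in the controls. Clusters of linked introns were tested with diffSpliceDGE, with junctions of at least 12 reads and 1% of the reads of a donor or acceptor. Library measures were compared with exact permutation tests and exon features with permutation tests of 100000 resamples.

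The named genes are DDX46, then the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 100 junction reads and groups that do not overlap. The named exons are the 12 largest falls and 8 largest rises among called exons with a mean of at least 30 informative reads and groups that do not overlap, the named sites are the 5 largest changes each way, and for each list up to 4 members with the smallest adjusted p were taken, of which some are not reported here. Because the rule gave mostly mitochondrial exons when applied to all exons, and no call for sites over all junctions, the named exons and sites were taken by the same rule from exons and introns matched to GENCODE 29. This was decided after the results were seen.

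Fits were tested on simulated data with 200 changed items and a dispersion of 0.01, a set value not estimated from these libraries. The changed exons and sites were drawn from those with an intermediate share and a mean of at least 30 reads. The changed genes and clusters had more reads than the filters required. Recovery of items with fewer reads, with a larger dispersion or with a share near either end was not simulated and may be lower. Of genes changed by 1 on the log2 scale 99% were recovered (12200 genes), and of intron clusters 98% (105938 clusters). False calls made up 6.60% and 5.31% of the calls in these fits, and 5.78% in the fit of exons among matched introns, each above the 5% threshold. Of such exons changed by 1.2 in natural log odds 72% were recovered in the fit over all exons and 81.5% in that among matched introns. For 3' sites these shares were 76% and 84.5%, for 5' sites 86% and 88.5%, and for linked introns, with 1 junction changed 3-fold, 96.5%. When junctions listed in some libraries only were added to the simulation, recovery was 23% for exons, 26% for 3' sites and 53% for 5' sites, and false calls made up 22.0%, 11.9% and 7.02% of the calls at the 5% threshold, against 4%, 3.18% and 2.82% without such junctions. The counts over all exons come from a fit that holds such junctions. The fit of exons matched to GENCODE 29 was not simulated.

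Depth was 21474228 to 23211279 unique junction reads per library. Alternatives were DESeq2 1.42.0 or its size factors, other read minimums and distances, multi-mapped reads, junctions matched to the annotation, a replicate block and each library left out. Sequence of flanking introns was not analysed here. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9 was used for all other steps.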

Results

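Junction reads were counted in 6 RNA-seq libraries of HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. In 3 libraries the cells had received an siRNA against PRP5, and in the other 3 a negative control siRNA, each at 30 nM for 48 h. PRP5 is the DEAD-box ATPase encoded by DDX46, which acts with the U2 snRNP when the branch site of an intron is recognised. The question set by the design is which splicing choices differ after the knockdown. The series has no other PRP5 siRNA group and no group with PRP5 restored. Effects of losing PRP5 therefore cannot be told from other effects of the siRNA. Uniquely mapped junction reads came to 22555815, 22043132 and 21570488 in control replicates 1, 2 and 3, and to 21474228, 22568963 and 23211279 in the knockdown replicates. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 5.10 to 7.78, against 85.4 to 98.1 between groups.

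DDX46 itself fell in all 3 knockdown libraries. Its junctions had 5302, 5707 and 5375 unique reads in the controls and 915, 910 and 805 in the knockdown. This corresponds to 243 ± 10.6 CPM (counts scaled by library total and TMM factor) in the controls and 44.4 ± 4.86 in the knockdown (SD, n = 3), a 5.47-fold lower level (log2 fold change −2.45, SE 0.065, edgeR adjusted p = 1.3e-21). The gene (ENSG00000145833.15) was placed on the plus strand of chromosome 5, where its matched introns spanned 134094646 to 134190587 in hg19.

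Among the genes with the largest rises, TPM4, which encodes a tropomyosin of the actin cytoskeleton, rose from 52.5 ± 5.16 to 328 ± 20.5 CPM (SD, n = 3; log2 fold change 2.64, SE 0.064). SAT1, the acetyltransferase of polyamine breakdown, rose from 169 ± 28.2 to 1049 ± 79.6 CPM (2.64 on the log2 scale). INSIG1, which holds the sterol-sensing SREBP complex in the endoplasmic reticulum, rose from 58.9 ± 0.567 to 277 ± 4.38 CPM (2.23), and HSPA5, the main chaperone of that compartment, rose from 649 ± 26.8 to 2574 ± 189.8 CPM (1.99). The other 8 of the 12 largest rises were HABP4 (2.16), ARRDC4 (2.05), RGS16 (2.02), KLF6 (2.00), RSRP1 (2.00), TSC22D3 (1.98), ICAM5 (1.98) and NEFM (1.96), among them a zinc finger transcription factor (KLF6) and a neurofilament subunit (NEFM).

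Among the genes with the largest falls, NCOA5, a nuclear receptor coregulator, fell from 29.4 ± 0.777 to 2.12 ± 0.193 CPM (SD, n = 3), which is 13.8-fold lower (log2 fold change −3.79, SE 0.14). PCF11, a subunit of the cleavage and polyadenylation machinery, fell from 24.1 ± 2.55 to 2.06 ± 0.861 CPM (−3.56), and PPP1R10, a nuclear targeting subunit of protein phosphatase 1, fell from 70.6 ± 3.91 to 9.20 ± 1.76 CPM (−2.94). PPP3CA, the catalytic subunit of calcineurin, fell from 43.2 ± 3.38 to 6.56 ± 1.13 CPM (−2.72). The other 8 were CFAP44 (−3.60), HOXA3 (−2.78), SMAD7 (−2.67), RIPK1 (−2.65), PRKACB (−2.55), DACH1 (−2.54), AMMECR1 (−2.52) and SLC1A1 (−2.50).

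Of 12306 genes tested with edgeR's quasi-likelihood test, 3872 rose and 3936 fell at a Benjamini-Hochberg adjusted p under 0.05. Of these, 443 and 908 changed by at least 2-fold. Such changes are relative to the typical gene, which TMM sets near 0 (median −0.013). Scaled by total reads without TMM, 5053 genes whose tested exons all missed an adjusted p of 0.05 had a median of −0.17. A shift shared by most genes is therefore not measured, and the size of small changes depends on this scaling. So do the counts of list genes that rose or fell. The groups did not overlap in 66.9% of genes, where chance gives 10%. With the cluster of introns that share splice sites as the unit, 24173 of 107402 clusters were higher and 23285 lower. A junction read is counted only from a spliced molecule, so a lower count can come from less RNA or from less splicing of the same RNA.

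**Figure D1:**
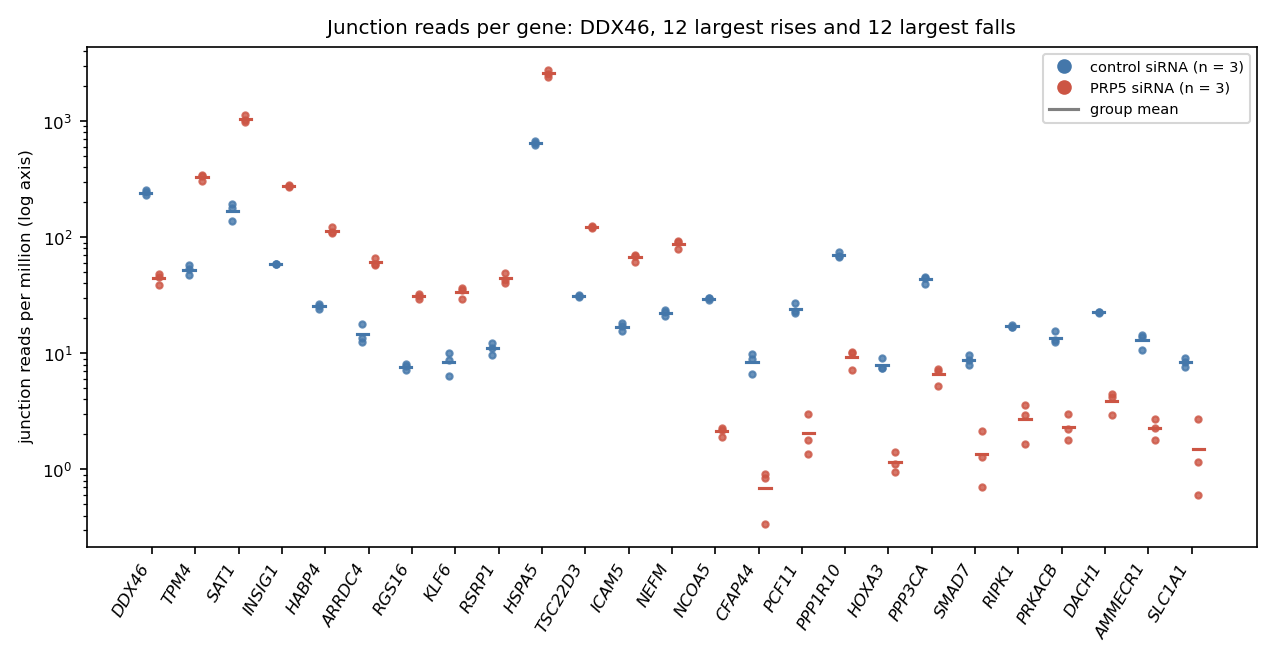
CPM of junction reads (log axis) of DDX46, the 12 genes with the largest rises and the 12 with the largest falls, with 1 point per library and a bar at the mean of each group (n = 3). DDX46 lies at 243 CPM in the controls and 44.4 in the knockdown, and the points of both groups do not overlap in any of these genes.

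Most measured genes of cytosolic ribosomal proteins and of oxidative phosphorylation rose, by modest amounts. Of 73 measured cytosolic ribosomal protein genes, 70 rose, 1 fell and 2 did not pass (71 past the threshold when adjusted over the list alone), with RPSA at 0.66, RPS2 at 0.57 and RPL4 at 0.54 on the log2 scale. Of 61 genes of oxidative phosphorylation, 53 rose, 2 fell and 6 did not pass (55 adjusted over the list alone), among them the cytochrome oxidase subunits COX7C and COX7A2 (both 0.94) and the complex I subunit NDUFV1 (0.85). Both lists ranked above other genes by camera with its preset correlation (adjusted p = 2.5e-10 and 3.7e-12). With an estimated correlation the calls were lost (adjusted p = 0.640 and 0.391).

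In lists of stress, heat shock and sterol genes, more genes rose than fell. In the list of the integrated stress response and unfolded protein response, 17 of 26 genes rose, 5 fell and 4 did not pass (23 adjusted over the list alone), including HSPA5, the stress-induced transcription factor ATF3 (1.84), the chaperone HSP90B1 (1.49) and HERPUD1 (1.11). Of 19 heat shock genes, 14 rose, 4 fell and 1 did not pass (18 adjusted over the list alone), with DNAJB1 at 1.53, HSPA8 at 1.08, HSPB1 at 1.02 and HSPD1 at 0.71. Of 25 genes of cholesterol synthesis, 14 rose, 6 fell and 5 did not pass (21 adjusted over the list alone), among them INSIG1, HMGCS1 (1.54) and FDFT1 (1.14). Camera placed these 3 lists above other genes (adjusted p = 1.7e-04, 3.7e-03 and 9.7e-05), and none held with an estimated correlation (adjusted p = 0.391 for each).

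Among splicing factors, genes of the U1 snRNP and Sm proteins rose, while members of the other groups went both ways. Of 15 U1 and Sm genes, 13 rose, 0 fell and 2 did not pass (14 adjusted over the list alone), with SNRPD2 at 0.83, SNRPG and SNRPA at 0.75 and SNRPF at 0.74 (camera adjusted p = 5.4e-05, and adjusted p = 0.391 with an estimated correlation). Of 24 genes of the U2 snRNP and its partners, 10 rose, 9 fell and 5 did not pass (19 adjusted over the list alone). The branch-site proteins PHF5A (1.02) and SF3B2 (0.89) and the U2 protein SNRPA1 (0.76) rose, while the DEAD-box protein DDX42 fell (−1.05). The median of that list (0.0034) and its mean (−0.024) differed in sign. In the tri-snRNP and catalytic spliceosome list, 15 of 37 rose, 11 fell and 11 did not pass (26 adjusted over the list alone), with PRPF38B at 1.11 and PRPF19 at −0.70. Of 10 minor spliceosome genes, 4 rose, 4 fell and 2 did not pass (8 adjusted over the list alone), with ZMAT5 at 0.70 and SNRNP25 at −0.52. Its median and mean were negative (−0.18 and −0.06) and the camera direction was up.

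Regulators of exon choice were divided too. Of 20 SR proteins and their kinases, 10 rose, 6 fell and 4 did not pass (17 adjusted over the list alone), with the kinase CLK3 at 1.17 and SRSF3 at −0.83. Of 29 hnRNP genes, 11 rose, 13 fell and 5 did not pass (24 adjusted over the list alone). HNRNPM (−1.71) fell, HNRNPC (0.66) and PCBP2 (0.53) rose, and the median of 0.02 and mean of −0.14 differed in sign. Of 15 genes of nonsense-mediated decay, 5 rose, 3 fell and 7 did not pass (8 adjusted over the list alone), with RNPS1 at 0.77 and the kinase SMG1 at −0.43. None of the lists of U2, tri-snRNP, minor spliceosome, SR, hnRNP and decay genes passed camera.

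More DNA repair genes fell than rose. Of 46 measured, 25 fell, 10 rose and 11 did not pass (35 adjusted over the list alone), among them the tumour suppressor BRCA2 (−1.50), the helicase BLM (−1.47) and FANCD2 (−0.76), while ERCC2 rose (0.69). Camera gave an adjusted p = 0.018, and with an estimated correlation the adjusted p = 0.391. Of 41 DNA replication genes, 13 rose, 14 fell and 14 did not pass (28 adjusted over the list alone), with the ribonucleotide reductase subunit RRM2 at 1.19 and POLA1 at −1.20. Of 40 mitotic genes, 19 rose, 15 fell and 6 did not pass (34 adjusted over the list alone). The mitotic motor KIF11 (−1.37) and CDC27 (−1.08) fell, and CDK1 (0.93) and UBE2C (0.88) rose. Neither the replication nor the mitotic list passed camera.

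Members of the remaining pathway lists moved in both directions, and none of these lists passed camera. Of 23 p53 targets, 10 rose, 7 fell and 6 did not pass (17 adjusted over the list alone), with PLK3 at 1.79, GADD45A at 1.62 and MDM2, the ubiquitin ligase of p53, at −1.34. Of 26 apoptosis regulators, 7 rose, 6 fell and 13 did not pass (13 adjusted over the list alone), with BCL2L1 at 1.02 and RIPK1 at −2.65. Of 29 genes of mTOR signalling and autophagy, 12 rose, 13 fell and 4 did not pass (25 adjusted over the list alone). GABARAPL1 rose (1.25) and TSC2 fell (−0.90), and the median of −0.05 and mean of 0.03 differed in sign. Of 17 interferon response genes, 1 rose, 4 fell and 12 did not pass (5 adjusted over the list alone), with BST2 at 1.34 and the RNA sensor RIGI at −1.36.

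Few markers of other cell types were measured, and in each such list more genes rose than fell. Among markers of HEK293 cells themselves more fell than rose. Of 7 fibroblast and endothelial markers, 3 rose, 1 fell and 3 did not pass (4 adjusted over the list alone). ACTA2 (1.93) and COL3A1 (1.32) rose and KDR fell (−0.64). COL1A1 rose by 0.15 with overlapping groups, and lost its call without control replicate 1 (0.14, adjusted p = 0.0577) and without knockdown replicate 3 (0.10, adjusted p = 0.111). Of 4 haematopoietic markers, 2 rose, 1 fell and 1 did not pass (3 adjusted over the list alone). LCP1 (0.98, overlapping groups) and CD68 (0.57) rose and CORO1A fell (−0.80), but without control replicate 2 the calls of LCP1 (0.67, adjusted p = 0.0572) and CD68 (0.43, adjusted p = 0.0801) were lost. Of 4 keratinocyte and carcinoma markers, 2 rose, 0 fell and 2 did not pass (2 adjusted over the list alone), with CDH3 at 0.90 and KRT8 at 0.58. Of 7 neuronal and renal precursor markers of HEK293 cells, 2 rose and 5 fell (7 adjusted over the list alone), with NEFM and VIM (0.78) up and LHX1 (−1.35) and PAX2 (−0.95) down. Its median and mean were negative (−0.49 and −0.20) and the camera direction was up, and for the haematopoietic list the median and mean were positive (0.31 and 0.20) and the direction down. None of these 4 lists passed camera. The mixed test of fry, which asks whether members change in either direction without comparing them with other genes, passed in all 23 lists (largest adjusted p = 0.00958), and its directional test in 12.

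**Figure D2:**
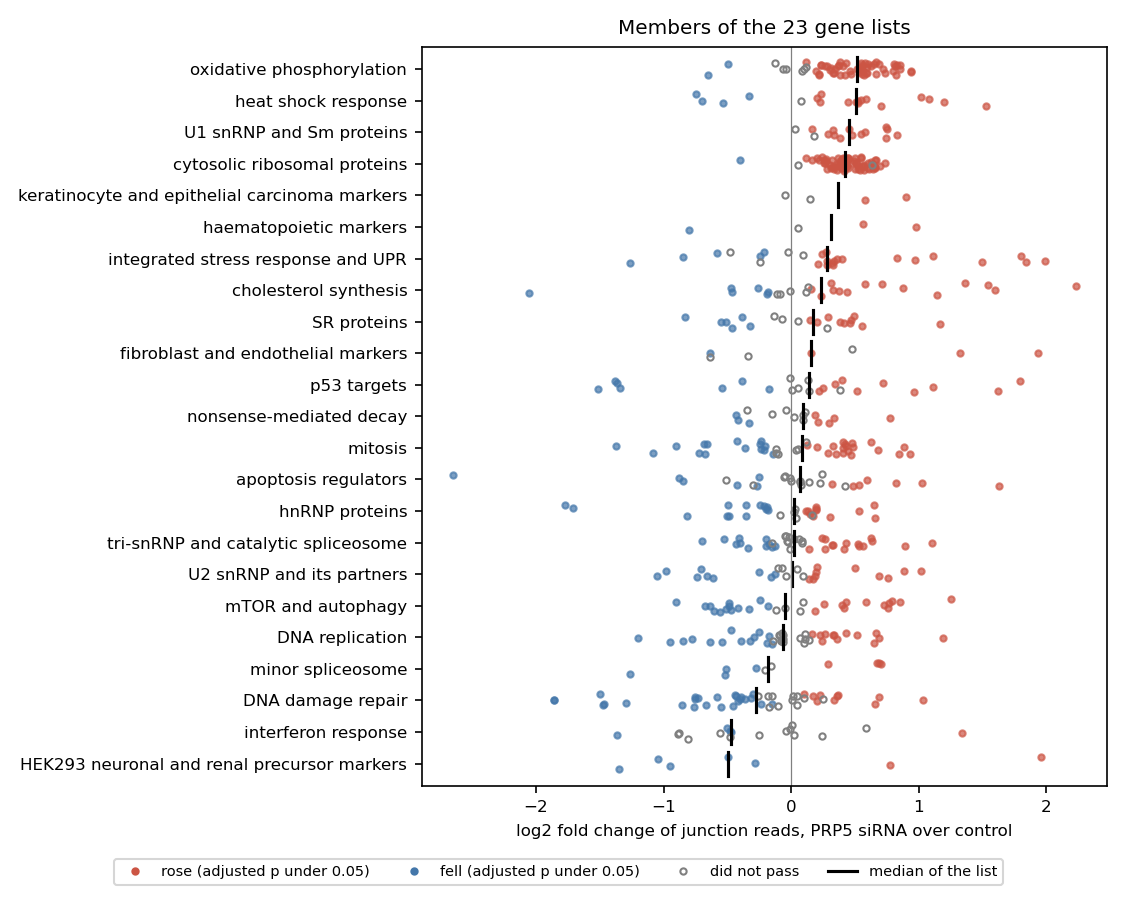
Log2 fold change of junction reads (PRP5 siRNA over control) of each measured member of the 23 gene lists, with filled points for genes past an adjusted p of 0.05, open points for the others and a bar at the median of each list. Oxidative phosphorylation has a median of 0.52 and the cytosolic ribosomal proteins of 0.42, and DNA damage repair of −0.28.

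Many exons were skipped more often after the knockdown. DBR1, the enzyme that opens intron lariats, lost most of an 81 nt exon (chromosome 3, 137882620 to 137882700, minus strand, hg19), whose inclusion (PSI, percent spliced in) fell from 91.6 ± 7.94 to 15.3 ± 8.43% (SD, n = 3; edgeR adjusted p = 2.2e-06). A 126 nt exon of HMGCS1, the synthase that feeds the sterol pathway (chromosome 5, 43298111 to 43298236, minus strand), fell from 94.9 ± 4.39 to 34.7 ± 3.74% (adjusted p = 9.5e-08). A 123 nt exon of the membrane-bending protein PACSIN2 (chromosome 22, 43272894 to 43273016, minus strand) fell from 87.4 ± 1.73 to 28.8 ± 3.64% (adjusted p = 1.5e-08). In MAPK8IP3, a scaffold of JNK signalling, a 126 nt exon (chromosome 16, 1794979 to 1795104, plus strand) fell from 74.4 ± 10.6 to 3.67 ± 1.07%.

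The other 8 of the 12 largest falls lay in TRIM59 (70 nt, 71.1 to 5.58%), PRKAA2 (94 nt, 84.8 to 20.2%), SENP5 (84 nt, 71.4 to 9.85%), RBM5 (61 nt, 71.5 to 11.05%), ZDHHC6 (162 nt, 95.5 to 35.1%), MBNL1 (36 nt, 92.5 to 32.7%), INPP4A (33 nt, 87.9 to 30.1%) and MED31 (97 nt, 72.9 to 15.4%). RBM5 and MBNL1 are themselves regulators of splicing. Inclusion rose in a 267 nt exon of ECT2, an exchange factor of cytokinesis (chromosome 3, 172536338 to 172536604, plus strand), from 12.2 ± 3.91 to 64.6 ± 1.99%. It also rose in a 312 nt exon of KIF23, a motor of the same process (chromosome 15, 69733107 to 69733418, plus strand), from 48.2 ± 5.29 to 92.6 ± 0.157%, and in a 38 nt exon of MRPL55 from 36.5 ± 2.89 to 86.8 ± 3.33%. The other rises were in EIF3M (12.99 to 57.2%), ADGRB2 (57 nt, 47.2 to 87.8%), a pair of overlapping exons of FAM193B (29.8 to 72.4% and 34.2 to 76.0%) and SMPD4BP (7.04 to 53.3%), whose reads may be shared with its near-identical copy SMPD4, so that its value is uncertain.

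These exons match an internal exon of the GENCODE 29 annotation by structure, a choice made after the values over all exons had been seen. Of 17205 such exons tested, 2103 in 1621 genes were less included and 332 in 291 genes more included, so that 86.4% of the changes were falls. Over all 29338 exons, the set fixed beforehand, 2069 in 1339 genes were less included and 497 in 311 genes more included (80.6% falls). There, 18 of the 20 exons with the largest changes lay on the mitochondrial chromosome and the other 2 at unannotated exons of EEF1A1 and EEF1G, with junctions listed in some libraries of a group only. Over all exons the calls dropped to 325 less and 57 more included when multi-mapped reads were added. Without control replicate 1, 2 or 3 they numbered 1325, 1222 and 1352 less included and 298, 259 and 292 more included, without knockdown replicate 1 or 2 they numbered 1091 and 1141 less included and 236 and 246 more included, and without knockdown replicate 3 the more included exons numbered 322.

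**Figure D3:**
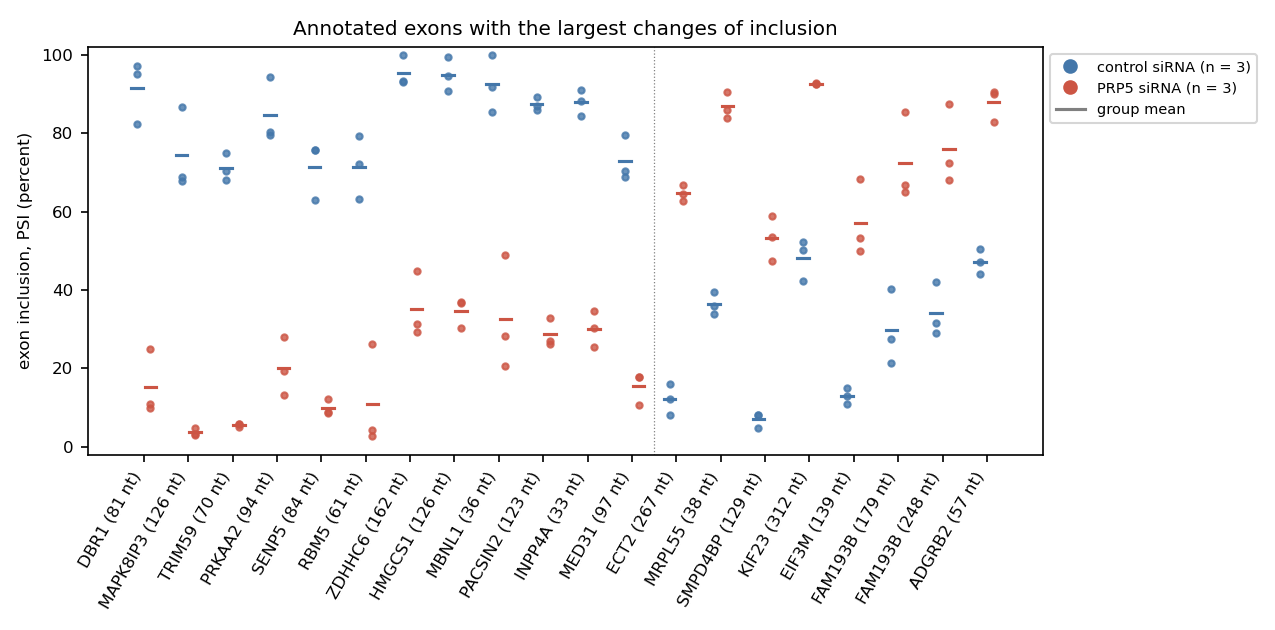
Inclusion (PSI in percent) of the annotated exons with the 12 largest falls, left of the dotted line, and the 8 largest rises, right of it, with 1 point per library and a bar at the mean of each group (n = 3). The DBR1 exon goes from 91.6 to 15.3% and the ECT2 exon from 12.2 to 64.6%.

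Exons of splicing regulators and of repair genes were among those that changed, with the following examples chosen after their values were seen. PUF60, a partner of U2AF at the 3' splice site, included a 51 nt exon at 44.7 ± 1.44% in the controls and 15.5 ± 2.26% in the knockdown (SD, n = 3; edgeR adjusted p = 9.4e-07). A 57 nt exon of the polypyrimidine tract binding protein PTBP1 fell from 52.6 ± 1.22 to 21.8 ± 0.695%, and exons of HNRNPR and HNRNPD fell from 90.2 to 66.7% and from 69.98 to 47.4%. In the kinase CLK1 a 91 nt exon rose from 58.8 ± 2.14 to 92.0 ± 2.06%, and in CLK4 a 59 nt exon fell from 21.5 to 1.54%. Both belong to the list of SR proteins and their kinases. Of its 18 genes tested among matched exons, 5 had a more included and 2 a less included exon. Of 7280 genes in all these were 291 and 1620, and the excess of rises in the list was not tested. The checkpoint kinase CHEK1 included a 96 nt exon at 93.0 ± 3.15% against 56.1 ± 6.03%, and FANCD2 a 74 nt exon at 89.1 ± 2.41% against 42.1 ± 6.83%.

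No cytosolic ribosomal protein gene and no gene of oxidative phosphorylation had an exon called less included. Over all exons these were 0 of 63 and 0 of 47 tested genes, against 1338 of 7912 genes (16.9%) in all (Fisher's exact test, two-sided, adjusted p = 0.00028 and 0.0031 over 23 lists). Among matched exons they were 0 of 62 and 0 of 42, against 1620 of 7280 (22.3%; adjusted p = 5.7e-06 and 4.9e-04). A gene entered these tests with as few as 12 reads of the rarer form, while a call needs a change of at least 0.1. Genes were not matched on read depth, control inclusion or number of tested exons. The tests therefore do not tell a trait of these lists from such differences. More inclusion was called in 4 ribosomal protein genes over all exons and in 2 among matched exons, RPL17 (6.86 to 17.2%) and RPS7 (87.7 to 100%, SD 21.3 in the controls), where the change in RPS7 rests on control replicate 1 alone (63.1%), since the other 5 libraries were at 100%. None of the other lists passed the same exact test: repair genes had 12 of 39 (p = 0.030, adjusted p = 0.221), decay genes 5 of 12 (p = 0.038, adjusted p = 0.221), hnRNP genes 9 of 29 and U2 genes 6 of 18 (adjusted p = 0.343 for both).

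Alternative 3' splice sites, the choice nearest to the branch site, changed in both directions. SRP19, a subunit of the signal recognition particle, used an acceptor 32 nt downstream of the site most used over all libraries in 67.7 ± 4.07% of reads in the controls and 21.96 ± 3.58% in the knockdown (SD, n = 3; edgeR adjusted p = 1.2e-06; intron 112200430 to 112203100 of chromosome 5, plus strand). Use of the alternative site also fell in RALGDS (64.7 to 29.8%), ZNF746 (47.3 to 15.5%), B4GALNT1 (51.6 to 13.6%) and CIT (44.7 to 13.5%). In SRP19, RALGDS and B4GALNT1 the site that fell was, on average, the more used one in the controls. In the focal adhesion protein PXN an acceptor 144 nt upstream rose from 9.92 ± 3.09 to 60.9 ± 19.8% (adjusted p = 4.0e-04), and rises were also seen in ELMO2 (12.9 to 60.2%), LARGE2 (17.7 to 62.8%), DHX34 (24.1 to 61.3%) and the sterol regulator SREBF1 (9.96 ± 9.09 to 52.9 ± 23.9%). The call of B4GALNT1 was lost without knockdown replicate 1 (adjusted p = 0.0595). That of CIT was lost without control replicate 2 (0.0693), knockdown replicate 1 (0.0582) or knockdown replicate 2 (0.134) and with DESeq2 (0.0605), and that of SREBF1 without control replicate 1 (0.0583), control replicate 2 (0.0621) or knockdown replicate 2 (0.0805).

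Alternative 5' splice sites changed likewise. In ENTPD4 the alternative donor fell from 63.0 ± 9.67 to 21.3 ± 11.4% (SD, n = 3; edgeR adjusted p = 0.0014), with falls in ADGRB2 (53.4 to 13.1%), ZMYND8 (45.1 to 5.41%), MATCAP2 (50.0 to 14.1%) and OMA1 (44.7 ± 35.7 to 5.83 ± 3.72%). In ENTPD4 and ADGRB2 the donor that fell was, on average, the more used one in the controls. In TRAPPC14 a donor 80 nt downstream rose from 6.20 ± 3.15 to 60.8 ± 6.47% (adjusted p = 3.1e-06; intron 99754838 to 99754915 of chromosome 7, minus strand). Rises followed in UBXN8 (15.3 to 65.5%), DDX51 (18.9 to 66.2%), the kinesin light chain gene KLC1 (28.4 to 75.5%) and CEP170 (26.2 to 71.8%). The call of OMA1 was lost without control replicate 1 (adjusted p = 0.0586), control replicate 3 (0.0538) or knockdown replicate 2 (0.0952) and with DESeq2 (0.0543).

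These sites come from introns matched to GENCODE 29, again a choice made after the values over all junctions had been seen. Among 3391 such 3' site events, 75 alternative sites were used more and 58 less, and among 2594 5' site events 94 and 78. For 3' sites, 48 upstream sites were used more and 24 less, against 27 and 34 downstream (Fisher's exact test, two-sided, p = 0.0138, adjusted p = 0.0275), and for 5' sites 41 and 30 upstream against 53 and 48 downstream (p = 0.536, adjusted p = 0.536). Both of these tests were chosen after the counts were seen. Of 316 3' site events 10 to 30 nt upstream, 5 were used more and 4 less, so the upstream excess lies mostly at other distances. Of 258 5' site events 10 to 30 nt upstream, 11 were used more and 3 less. These narrower counts were not tested. Some of the called site events are exon skipping counted as a site choice. In these a further junction of at least 12 reads joins an exon lying between both sites. This held for 14 of the 75 and 9 of the 58 3' sites, with DHX34 and SREBF1 among them, and for 11 of the 94 and 12 of the 78 5' sites. The fall in ADGRB2 is the rise of its 57 nt exon given above. Without these events the 3' sites numbered 61 and 49, with 40 more and 21 less used upstream against 21 and 28 downstream (Fisher's exact test, two-sided, p = 0.0212, adjusted p = 0.0423), and the 5' sites 83 and 66, a set also chosen after the counts were seen. Over all junctions, the set fixed beforehand, edgeR called 0 of 8713 3' site events (smallest adjusted p = 0.252, 922 at an unadjusted p under 0.05) and 0 of 5250 5' site events (smallest adjusted p = 0.0863, 898 at an unadjusted p under 0.05), where DESeq2 called 85 more and 54 less used 3' sites and 83 and 53 5' sites. Among matched introns DESeq2 called 35 and 21 3' sites and 52 and 37 5' sites. Without control replicate 1 the 3' counts were 49 and 33, without knockdown replicate 1 they were 47 and 36, without knockdown replicate 2 the less used sites numbered 33, and without control replicate 3 the more used 5' sites numbered 62.

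Of 24421 clusters of introns linked by shared splice sites, which also cover several exons skipped together, 2589 (10.6%) changed in junction use (edgeR's diffSpliceDGE, Simes adjusted p under 0.05). Without control replicate 1 or 2 the count was 1725 or 1679, with multi-mapped reads 941, and with the F test per cluster 5759.

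At the level of whole libraries, reads that skip a mostly included exon made up 0.533 ± 0.00748% of junction reads in the controls and 0.684 ± 0.0174% in the knockdown (SD, n = 3), a difference that was 0.0905 percentage points with multi-mapped reads. At an equal depth of 21474228 reads, 272696 ± 1294 junctions were seen in the controls and 254406 ± 339 in the knockdown, and the median length of the introns read was 889.7 ± 13.8 and 825.0 ± 6.56 nt. Among junctions with at least 5 reads over the 6 libraries the difference, knockdown minus control, was −5411, so most of the loss lies in junctions with fewer reads. Reads on junctions unmatched to the annotation made up 4.34 ± 0.0662 and 4.60 ± 0.0193%, and those on non-canonical junctions 0.0711 ± 0.00213 and 0.0783 ± 0.000562%. In each of these 5 measures the groups did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow (adjusted p = 0.18 over 9 measures). Reads on AT-AC introns, the class typical of the minor spliceosome, made up 0.113 ± 0.00192 and 0.109 ± 0.00238% (exact p = 0.2), and those on GC-AG introns 0.840 ± 0.0241 and 0.829 ± 0.0078% (exact p = 0.5). Multi-mapped reads made up 5.72 ± 0.112 and 5.86 ± 0.0849% (exact p = 0.2), and junctions without the annotation mark of the files 0.00080 and 0.00078% (exact p = 0.8).

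Less included exons were shorter and lay between longer introns than exons without change, and more included exons the reverse. Over all exons, the median length was 97.0 nt for 2069 less included exons and 144 nt for 497 more included exons, which is −21.0 and 26.0 nt against the median of 9481 exons without change. The upstream intron had a median of 2512 nt in less included, 598 nt in more included and 1832 nt in unchanged exons, and the downstream intron 2166, 474 and 1825 nt in the same order. In two-sided permutation tests of medians with 100000 resamples, p was 3.0e-05 for the downstream introns of less included exons and 1e-05, the smallest these resamples can give, for the other 5 comparisons (adjusted p = 1.2e-05). Among matched exons the medians were 93.0, 137 and 109 nt for exon length, and 2835, 836.5 and 2175.5 nt for the upstream intron. For the downstream intron they were 2356, 648.5 and 2090.5 nt. There the difference of less included exons was the weakest (permutation test, p = 0.0039). Exons without change had an adjusted p over 0.5 in edgeR's test and a PSI change under 0.05. They were not matched with the changed exons on read depth or control inclusion. Exons are not independent replicates, so these tests describe which exons changed.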

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

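Results among matched exons and introns, the gene sums, the estimated correlation in camera, the site events without an exon between the sites and the alternative without mitochondrial events and junctions listed in some libraries only were chosen after the data were seen. No called result reversed. The sign of 2 library measures without a call was not fixed: with a library left out, the difference in reads on GC-AG introns ran from −0.0239 to 0.000168 percentage points and that in reads without the annotation mark from −9.78e-05 to 3.89e-05, the latter also above 0 with at least 5 reads or an overhang of at least 20 nt. The level of DDX46 stayed between −2.36 and −2.52 on the log2 scale, and the counts of genes and of abundance clusters stayed within 1.5 times under every alternative. So did those of lists past camera with its preset correlation, while with an estimated correlation 0 lists passed (smallest adjusted p = 0.391). Where a count moved further, the cause was not tested unless stated. Over all exons, adding multi-mapped reads gave 325 less and 57 more included exons, of which 307 of the 325 were also called with unique reads. Junctions matched to the annotation gave 1242 and 310, no minimum change gave 3385 and 1256, and a minimum of 0.2 gave 1272 and 294, the last 2 by construction. Leaving out each library in turn gave 1091 to 1492 less and 236 to 322 more included exons, and among matched exons 1668 to 1969 and 248 to 296. For 3' sites over all junctions, where edgeR called 0, DESeq2 gave 85 more and 54 less used sites, matched introns 75 and 58, and the set without mitochondrial events and junctions listed in some libraries only 7 and 2. For 5' sites these counts were 83 and 53, 94 and 78, and 78 and 53. Among matched introns DESeq2 gave 35 and 21 3' sites and 52 and 37 5' sites, and leaving out each library gave 47 to 69 and 33 to 52 3' sites and 62 to 86 more used 5' sites. Linked intron clusters numbered 941 with multi-mapped reads, 5759 with the F test and 1679 to 2004 with a library left out. The alternative with a mean of at least 3 reads was not run for these clusters, since the junction minimum already implies it.

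Of the library measures, given as knockdown minus control, multi-mapped reads moved the share of reads without the annotation mark to −0.000184, that on AT-AC introns to −0.0157 and that skipping a mostly included exon to 0.0905 percentage points. Junctions with at least 5 reads gave 0.325 points for unmatched reads and −5411 junctions at equal depth, and an overhang of at least 20 nt gave −17138 junctions. For single named genes 1413 values kept their side of the threshold and 4 did not, and for named events 486 did and 64 did not, most of these mitochondrial. Scaling with DESeq2 size factors shifted the median of all genes by 0.0089 on the log2 scale. Those factors, like TMM, take most genes as unchanged, so a shift shared by most genes was not tested. With 3 libraries per group, library measures cannot reach a p under 0.1.

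Replicate numbers are shared by both groups, and whether they pair the samples stays open. Deviations of same-numbered libraries correlated at 0.059, 0.239 and 0.073, and those of differently numbered libraries at −0.179 to 0.120. Control replicates 2 and 3 correlated best with the knockdown replicate of their own number. Control replicate 1 correlated best with knockdown replicate 3 (0.120). With the replicate number as a block, 3895 genes rose and 3968 fell, and 2123 exons were less and 555 more included. Changed clusters of linked introns numbered 3696, against 2589 without the block. No count moved by more than 1.5 times.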

Other observations

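The tests of junctions listed in some libraries only, of junctions unmatched to the annotation and of other splits of the libraries were chosen after the results they bear on were seen. Zinc finger genes, many of which encode KRAB repressors of transposons, fell more often than they rose. Of 369 measured genes with symbols starting ZNF, 146 fell, 36 rose and 187 did not pass edgeR's test, with a median log2 fold change of −0.40. The hypothesis that they lie below other genes was tested with camera (p = 0.0099 with the preset correlation and p = 0.0401 with an estimated correlation), and with adjustment over the 4 families tested the latter did not pass (adjusted p = 0.160). Mitochondrial ribosomal protein genes (MRPL and MRPS), whose products translate the mitochondrial mRNAs, included 40 that rose, 13 that fell and 18 that did not pass among 71, with a median of 0.25. Camera gave p = 0.0015 with the preset correlation, and the call was lost with an estimated correlation (p = 0.159). These families were chosen after the gene lists had been tested and before their own values were computed. Of 36 proteasome genes 13 rose, 9 fell and 14 did not pass (p = 0.768 with an estimated correlation), and of 17 cytosolic aminoacyl-tRNA synthetase genes 9 rose, 3 fell and 5 did not pass (p = 0.477).

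Genes with a less included exon tended to lose junction reads. Of 1338 such genes 633 fell and 319 rose. Comparison genes had tested exons and none at an adjusted p under 0.05 in edgeR's test, whatever the change. Genes with an exon past that threshold but none called less included were in neither group. Of 5390 comparison genes 1673 fell and 1976 rose. The medians were −0.18 and 0.04 on the log2 scale, a difference of −0.227 (permutation p = 1e-05, the smallest 100000 resamples can give). Skipping an exon gives 1 junction in place of 2, so part of this can come from counting. Junctions that overlap no tested exon or its introns were compared too, scaled by total reads without TMM. There the medians were −0.32 in 1230 genes with a less included exon and −0.17 in 5053 comparison genes. Their difference was −0.141 (permutation p = 1e-05). Over all junctions of the same genes the medians were −0.39 and −0.17 on that scale. The difference there was −0.219 in edgeR's fit, which argues against counting as the whole cause. The remaining −0.141 is in the direction of a hypothesis that exon skipping goes with lower abundance. Both groups of genes were not matched on span, read depth or number of tested exons. The difference therefore cannot be told from one in these traits. The data also do not tell decay of the skipped mRNA from less splicing. Across 12224 genes the fold change also fell with the genomic span of the gene (Spearman rho −0.142, Pearson r −0.112), and less so with the number of introns (rho −0.0853, r −0.041), each with permutation p = 1e-04 for rho, the smallest 10000 resamples can give. Genes are not independent replicates, and the value for introns lies between the bounds set beforehand, so that hypothesis stays open.

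Less included exons had a lower GC content than exons without change, with no matching on read depth, control inclusion or intron length. Among exons of the whole set that match an annotated exon, the median was 45.3% in 1556 less included and 51.1% in 5401 unchanged exons, a difference of −5.78 percentage points, and 57.2% in 214 more included exons (permutation p = 1e-05 for both, the smallest 100000 resamples can give). The hypothesis that skipped exons preserve the reading frame was tested by exon length. A length divisible by 3 was found in 48.5% of less included and 41.6% of unchanged exons, a difference of 6.88 percentage points (Fisher's exact test, two-sided, p = 1.6e-06), which did not reach the share of 50% set beforehand, so this stays open. More included exons matched the annotation in 43.1% of cases and less included exons in 75.2%.

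The first pattern weighed is the loss of junction reads toward the 3' end of long genes. In 8060 genes with at least 6 introns and a mean of at least 30 reads per tercile, the median log2 change of the 3' tercile of introns against the 5' tercile was −0.006, −0.02, −0.03, −0.06 and −0.17 from the shortest to the longest quintile by span, and in the longest quintile −0.17, −0.22 and −0.16 in the 3 knockdown libraries. RNA fragmentation or a 3' bias acting alike on all genes is argued against, since the longest and shortest quintiles differ by −0.165 (permutation p = 1e-05, the smallest 100000 resamples can give). Fragmentation that acts on mRNA length stays open: within quintiles of mRNA length, genes of longer span lay lower by −0.0651 on average, with differences from the shortest to the longest mRNAs of 0.0002 (permutation p = 0.982), −0.03 (p = 0.00876), −0.04 (p = 0.00092), −0.09 and −0.17 (p = 1e-05 for both, the smallest possible), where all 5 quintiles had been required to differ. A candidate explanation is that transcription ends early or stalls within long genes after the knockdown. The value of −0.171 in the longest quintile is in the range set beforehand for it, but the same value defines the pattern. It therefore cannot tell this explanation from the fragmentation left open above. Junction reads also do not tell less RNA from less splicing toward the 3' end.

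The second pattern is that more exons lost than gained inclusion. Junctions unmatched to the annotation are argued against as its source, since 80.0% of the called exons fell among matched introns. A ceiling of inclusion in the controls stays open. Among called exons with a control PSI of 0.3 to 0.7, 296 fell and 149 rose, so that 66.5% fell (95% Clopper-Pearson interval 61.9 to 70.9%, counting error only), between the bounds set beforehand. The knockdown itself, the difference the design names, is also open.

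The last pattern is the absence of calls at alternative 3' and 5' sites over all junctions, against calls among matched introns. The number of events to correct for is argued against: with the p-values of the fit over all junctions, adjusted over the matched events alone, 0 events were called. Junctions listed in some libraries only may account for it. Events with a form at 0 reads in 1 library and at least 15 in another of the same group made up 12.3% of 3' and 8.15% of 5' events, and in 1.27% of them the alternative junction was a matched intron. Without these and the mitochondrial events, which were left out together, the 5' sites had 78 more and 53 less used sites, while the 3' sites had 7 and 2.

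The 6 libraries can be split 3 against 3 in 10 ways, so a share under 0.05 cannot be reached, and 1 of the 10 splits, the real one, gave as many calls for each of the following results. The real split and the highest other gave 47458 and 3 abundance clusters, 7808 and 0 genes, 2566 and 0 exons, 2435 and 0 matched exons, 133 and 0 3' sites and 172 and 0 5' sites among matched introns, and 2589 and 9 linked intron clusters. For 3' and 5' sites over all junctions, all 10 of the 10 splits gave 0 calls. Outside the nuclear genes, mitochondrial junction reads made up 0.191 ± 0.0279% of reads in the controls and 0.132 ± 0.0264% in the knockdown (SD, n = 3), which was not tested. The mitochondrial exons among the largest changes matched no annotated exon and had no reads in some libraries. These reads are therefore not taken as splicing of mitochondrial RNA.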
